A study of Mus musculus with 7 samples.

How the data were processed

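The samples were 7 mouse tumours, each from its own mouse per the labels, taken at week 4: 3 from mice given anti-KLH with anti-PD-1 (controls) and 4 from mice given anti-LAIR1 with anti-PD-1. The series text describes both tumours grown under the skin from a mouse lung cancer line and lung tumours of an engineered mouse model, with anti-LAIR at 10 mg/kg and anti-PD-1 at 8 mg/kg for the former, and the labels do not say which kind of tumour these 7 were. The names of the control mice begin with LOHM or KWM and those of all treated mice with WTSV. What these prefixes stand for is not given in the sources used here, and they separate the groups completely. No batch, sex or age is given for single mice.

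RNA was isolated with Trizol and a column kit, and directional libraries were made from polyadenylated RNA and sequenced as single reads on a NovaSeq instrument, per the labels' protocols. The authors deposited 1 table of raw read counts per gene symbol, 24421 rows with 1 column per mouse and 0 blank or summary rows. Per the submitters' processing notes, Trim Galore, STAR 2.7.6, featureCounts 2.0.1 and edgeR 3.40.1 were used with the mm10 build. The gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Reads of near-identical genes and of overlapping or antisense genes could therefore be split or lost, and counts of such genes are uncertain. The counts were used as deposited. Coordinates come from a RefSeq gene table of GRCm38, the assembly that mm10 names, in which 23204 symbols (95.0%) had a match, and are counted from 1.

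Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr for the group, which at its minimum count of 10 left 13545 genes, and libraries were scaled by TMM. Expression is given as CPM computed from the deposited counts with TMM-scaled totals, and values after ± are SDs over libraries of a group. Group differences, anti-LAIR1 minus control, came from the robust quasi-likelihood fit of all 7 libraries with no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.182. DESeq2 1.42.0 and limma 3.58.1 (voom with quality weights) were run as alternatives, and DESeq2 gave an adjusted p for 13924 genes. Log2 CPM used a prior count of 2. Per library, 3 counts are worth from 0.119 to 0.305 CPM, and intervals and such floors cover counting error only.

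Gene lists for the tissue and treatment, 42 in all, were fixed before the data were examined, and the 36 with at least 5 tested members (sex-linked genes were only described) were tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, fry, and an exact two-sided permutation test of each list's mean log2 CPM over the 35 splits of 3 against 4 stand beside it. Lists share members, so their calls are not independent. Named genes followed a rule fixed in advance. Up to 12 genes per direction past an adjusted p of 0.05 with an average log2 CPM of at least 1 and separated groups came first, and there were 0. Because fewer than 6 passed, the 6 genes with the smallest p were added. From each list came up to 4 members past the threshold, otherwise the 1 member with the smallest p, and Lair1, Pdcd1, Cd274, Col1a1, Col1a2, Col3a1, Cd8a, Cd4 and Ifng were taken in every case. Other genes were chosen after their values were seen: muscle, skin and fat genes, Ifit1, Cxcl9, Ptprc, Myo5c, Ly6a, Ace, Ido1 and further genes of the DESeq2 result, besides list members given to illustrate a list.

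On simulated counts for these libraries with genes changed by known factors, edgeR recovered 86% of the 100 genes changed by a factor of 2 and 95% of the 100 changed by a factor of 4, tested among 13428 genes, and also called 20 unchanged genes. DESeq2 recovered 91% and 98% among 13544 genes and called 53 unchanged ones. The changed genes were drawn only from well-counted ones, so recovery of genes with few counts was not measured. With nothing changed edgeR called 2 genes, DESeq2 17 and camera 0 of 36 lists. Genes were simulated independently of one another, so camera's 0 says nothing about lists whose genes move together. The recovery shares too were obtained without variation shared by the genes of a library, and may be too high for these tumours. In the real libraries Cxcl9 differed by a factor of 3.87 with an edgeR adjusted p of 0.633. A count of 0 genes therefore does not show that changes by a factor of 2 were absent. Alternatives covered scaling, the count filter, the test, leaving out each library, thinning to the smallest total, muscle level as a covariate and removal of abundant or sex-linked genes. A sex covariate was planned only if sexes differed, and was left out because all libraries held Y-linked counts. Figures were drawn with matplotlib 3.10.9.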

Results

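Polyadenylated RNA was sequenced from 7 mouse tumours whose titles give antibody treatment at week 4, without saying from which event the weeks are counted. All 7 mice received anti-PD-1, which blocks an inhibitory receptor of T cells. In 3 mice it was combined with anti-KLH, a control antibody against keyhole limpet haemocyanin, and in 4 mice with anti-LAIR1, which blocks a collagen-binding inhibitory receptor of leukocytes. Each library came from a separately named mouse. The total counts were 26255727, 13274458 and 9879762 in control replicates 1, 2 and 3, and 15347403, 15100728, 11480651 and 13253993 in anti-LAIR1 replicates 1, 2, 3 and 4. Across genes, which are not independent replicates, the Spearman correlation between libraries ranged from 0.977 to 0.991. Its median was 0.985 for pairs within a group and 0.984 for pairs across groups, and no pair of libraries differed as little as sampling noise alone would give.

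The comparison asks what LAIR1 blockade adds to PD-1 blockade in the tumour transcriptome. Interferon response genes were higher as a group with anti-LAIR1: all 21 measured type I interferon response genes and all 24 measured interferon gamma response genes had a positive fold change, with list medians of 1.04 and 1.12 on the log2 scale. Both passed camera at its preset correlation and missed the threshold otherwise (adjusted p = 0.058 and adjusted p = 0.121 with an estimated correlation). Lists of antigen presentation, T cell, cytotoxic, macrophage, chemokine and complement genes were also higher at the preset correlation, with medians from 0.42 to 1.26, and none of them passed with an estimated correlation (adjusted p from 0.058 to 0.220). Collagen genes and hypoxia and glycolysis genes were lower as lists at the preset correlation, with small medians of -0.17 and -0.19 (adjusted p = 0.257 and adjusted p = 0.284 with an estimated correlation), and the hypoxia and glycolysis call ended without control replicate 2 (camera adjusted p = 0.0573) and with the muscle level as a covariate (0.368). No single gene passed the test: edgeR's quasi-likelihood test gave 0 genes at an adjusted p under 0.05 among 13545 tested, and the smallest adjusted p was 0.175.

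By edgeR, 697 genes had an unadjusted p under 0.05, of which 476 were higher and 221 lower with anti-LAIR1, against 677 that chance gives. DESeq2 called 54 genes, 52 higher and 2 lower, and limma-voom called 0. The DESeq2 count lay between 23 and 94 without single libraries, with 18 and 40 of the 54 genes among these. Among the 35 splits of the libraries into 3 and 4, 7 reached 54, the real one included. The groups did not overlap for 414 higher and 340 lower genes, 5.57% of those tested against the 5.71% that chance gives. Of 36 gene lists tested with camera at a preset correlation of 0.01, 25 passed an adjusted p of 0.05, 20 higher and 5 lower, while other splits of the same 7 libraries into 3 and 4 gave from 4 to 23 such lists. With the correlation estimated from the data 0 lists passed, the smallest adjusted p being 0.058, and 10 lists had an unadjusted p under 0.05. In the exact permutation test of list means the smallest adjusted p was 0.206, and 5 lists reached the smallest possible p of 0.0286. Unadjusted, the test gave 0.114 for the interferon gamma, T cell and collagen lists and 0.0571 for the cytotoxic, chemokine and complement lists. It gave 0.143 and 0.171 for MHC class I and II, and 0.314 for hypoxia and glycolysis. Fry, which tests whether a list's genes move on balance one way, called 0 lists. Its mixed form, which tests for changes in either direction, called 4: complement (adjusted p = 0.00373), chemokines (0.0111), myeloid receptors (0.0115) and macrophages (0.0154). Leaving out anti-LAIR1 replicate 2 raised the edgeR count to 3 genes, Ttn, Neb and Acta1, all of striated muscle, and these were looked at only after their values were seen.

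**Figure D1:**
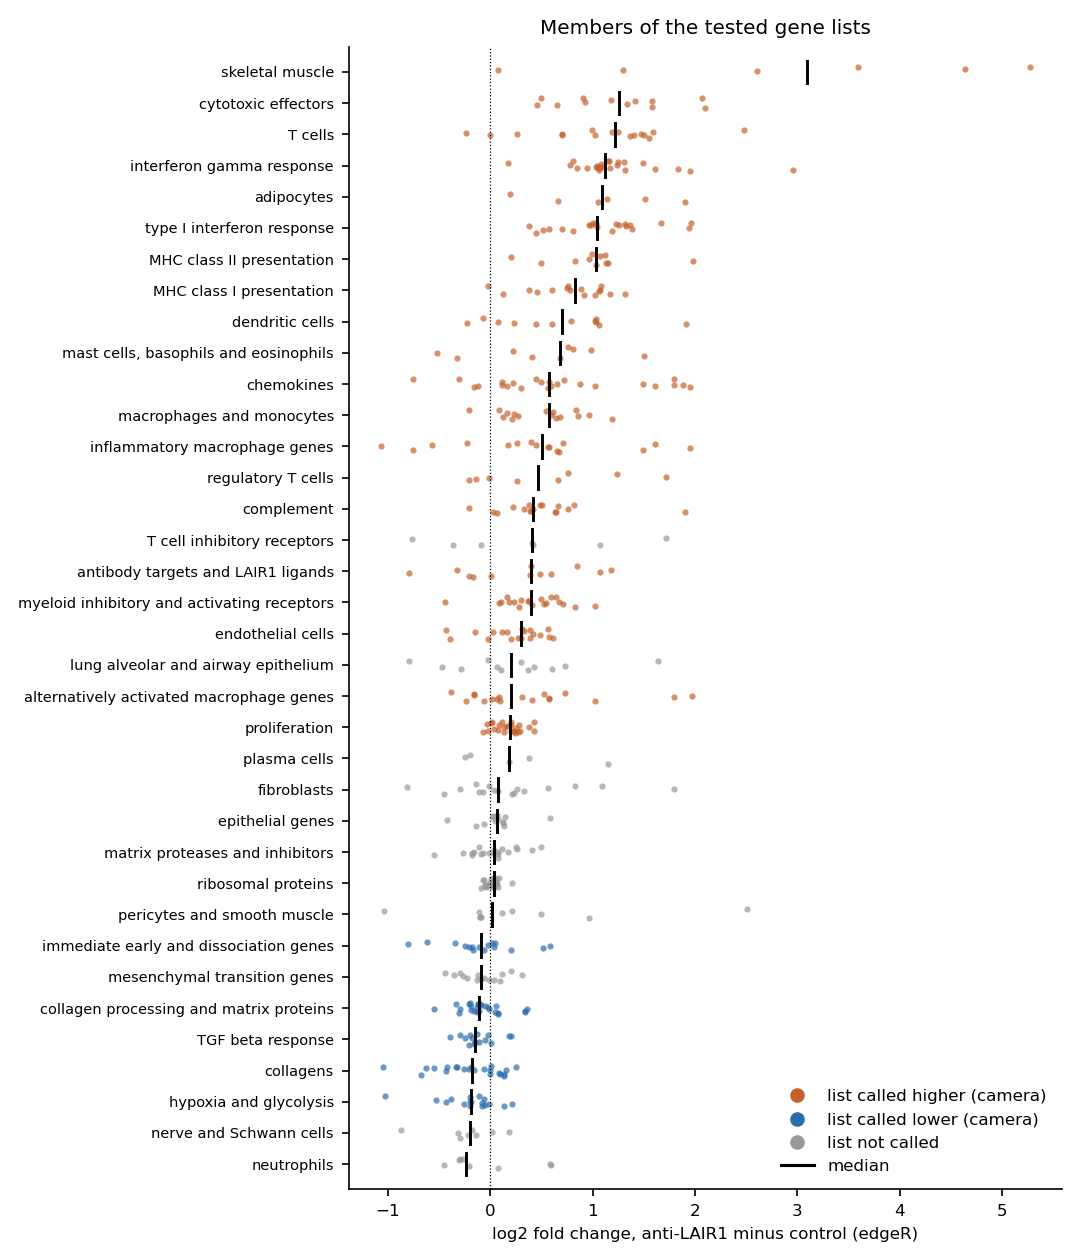
Each point is the edgeR log2 fold change (anti-LAIR1 minus control) of one member of a tested gene list, and black bars mark list medians. Orange lists were called higher and blue lists lower by camera at the preset correlation, grey lists were not called, and 0 of them passed with an estimated correlation.

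The 6 genes with the smallest p, none of which passed edgeR's adjusted test, included interferon-inducible, chemokine and complement genes. Rerg, which encodes a RAS-like GTPase (chromosome 6, 137054825 to 137170496, GRCm38), averaged 5.70 ± 0.886 CPM (SD, n = 4) with anti-LAIR1 and 1.30 ± 0.218 CPM (SD, n = 3) in controls. Its log2 fold change was 2.12 with an SE of 0.26 and an edgeR adjusted p of 0.175. Ccl8, a monocyte-attracting chemokine (chromosome 11, 82115185 to 82116799), averaged 12.8 ± 2.72 against 3.55 ± 1.29 CPM. Mx1, an interferon-induced antiviral GTPase (chromosome 16, 97447035 to 97462906), averaged 6.95 ± 2.53 against 1.78 ± 0.0775 CPM. The gene table used for coordinates lists Mx1 as a transcribed pseudogene, because the reference mouse strain carries a defective copy, so its level is read here as a response to interferon only. Cfb, complement factor B (chromosome 17, 34856374 to 34862514), averaged 109 ± 12.3 against 70.1 ± 5.37 CPM. Gbp10, an interferon-inducible GTPase (chromosome 5, 105215699 to 105239533), averaged 2.53 ± 0.686 against 0.471 ± 0.187 CPM. Gbp10 and its neighbour Gbp11 are close copies that share reads, so the split of counts between them is uncertain. Ankrd37, a gene induced in hypoxia (chromosome 8, 45996908 to 46000414), was the 1 gene of the 6 with a lower level, 10.2 ± 1.07 against 20.7 ± 4.93 CPM. The last 5 genes had log2 fold changes of 1.89, 1.96, 0.64, 2.39 and -1.03, and each had an edgeR adjusted p of 0.540. All 6 separated the groups completely, and all 6 were among the 54 genes DESeq2 called, Rerg with an adjusted p of 8.17e-07. Neither adds support, since the 6 were picked for their p in the same libraries.

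**Figure D2:**
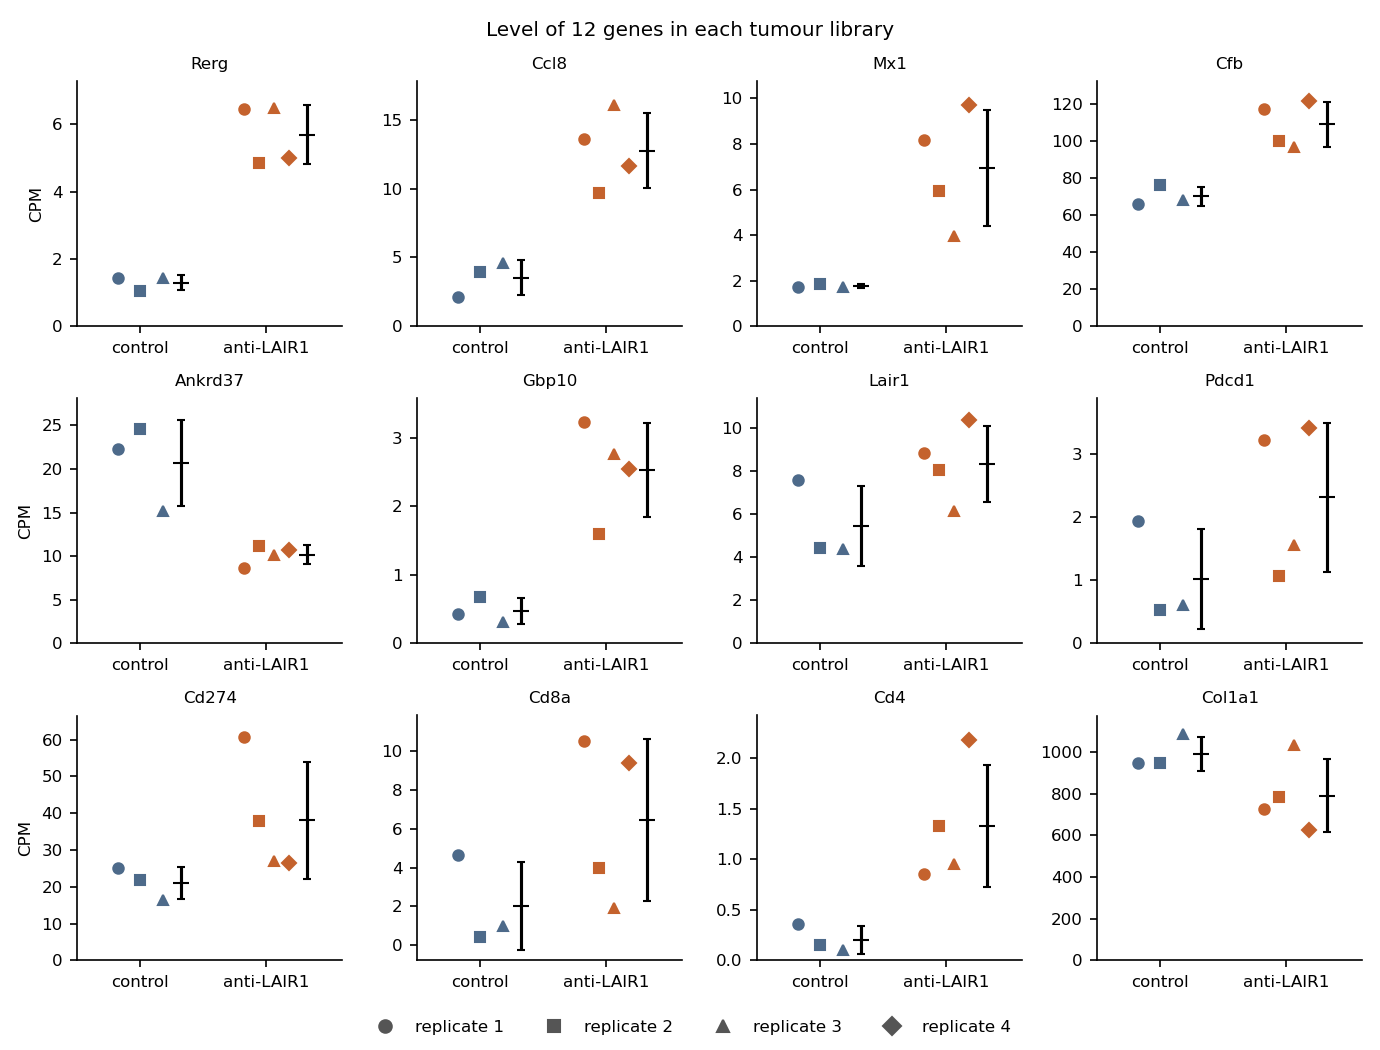
Level in CPM of 12 genes in each library, with control replicates in blue and anti-LAIR1 replicates in orange. Bars to the right of each group give the mean and SD (n = 3 controls, n = 4 anti-LAIR1), and the first 6 genes, Cd274 and Cd4 separate the groups while none of the 12 passed edgeR's adjusted test.

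The type I interferon list rose as a whole (camera adjusted p = 2.80e-41, adjusted p = 0.058 with an estimated correlation). Fold changes of its 21 members ran from 0.37 to 1.96, 19 passed when adjusted over the list alone, 0 over all genes tested, and 15 separated the groups. The list's mean log2 CPM was higher in each anti-LAIR1 library, from 3.79 to 4.76, than in each control, from 2.97 to 3.50 (exact permutation test, two-sided p = 0.0286, the smallest that 3 against 4 allows, and 0.206 after adjustment over the lists). Apart from Mx1, an example is Ifit1, an antiviral RNA-binding protein named here after its values were seen, with 32.8 ± 9.76 against 12.4 ± 3.76 CPM. The interferon gamma list also rose (camera adjusted p = 3.60e-28, adjusted p = 0.121 with an estimated correlation), with 15 of 24 members at an unadjusted p under 0.05, 4 when adjusted over the list alone, and 8 separating the groups. Cxcl10, a T cell-attracting chemokine, averaged 11.2 ± 6.06 against 3.66 ± 0.432 CPM, and Cd274, which encodes the PD-1 ligand PD-L1, averaged 38.0 ± 15.9 against 21.1 ± 4.40 CPM with a log2 fold change of 0.84 (SE 0.31, edgeR adjusted p = 0.935). The Cd274 fold change lay between 0.53 and 0.99 over the alternatives. Without control replicate 1, whose level was the highest of the controls, the interferon gamma median was 1.71. The lowest interferon gamma median in a fit that left out a library was 0.87. Members of the Ifit, Oas and Gbp families resemble one another, so single members carry some uncertainty from shared reads. Ifng itself was below the count filter and was not tested, at 0.22 ± 0.218 CPM in controls and 0.476 ± 0.196 with anti-LAIR1, close to the 0.119 to 0.305 CPM that 3 counts are worth in these libraries.

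**Figure D3:**
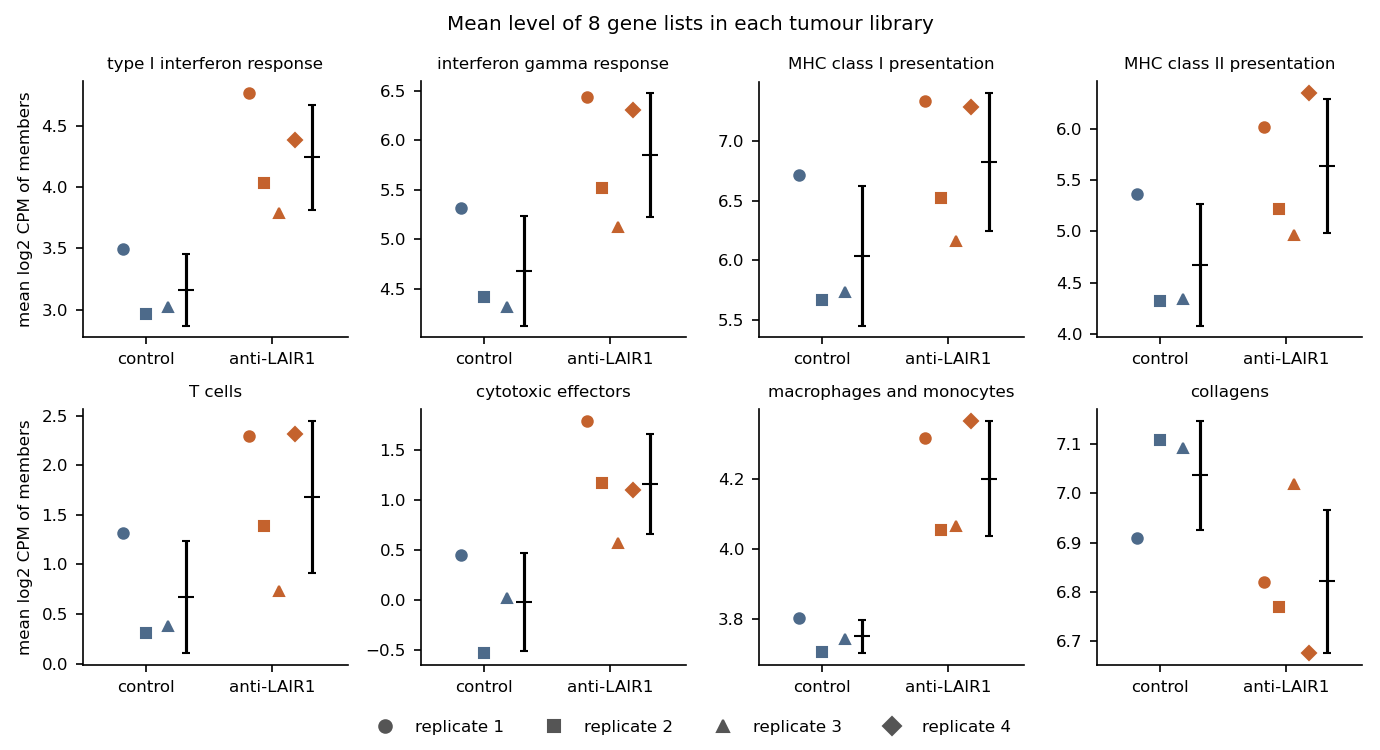
Mean log2 CPM of the tested members of 8 gene lists in each library, with control replicates in blue, anti-LAIR1 replicates in orange, and bars giving the mean and SD (n = 3 controls, n = 4 anti-LAIR1). Type I interferon and macrophage levels separate the groups, whereas control replicate 1 lies within the anti-LAIR1 range for the interferon gamma, T cell and MHC lists.

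Antigen presentation genes rose as lists. MHC class I presentation had a median of 0.83 over 16 members (camera adjusted p = 1.48e-10, adjusted p = 0.220 with an estimated correlation), and MHC class II presentation a median of 1.03 over 11 members (camera adjusted p = 5.40e-10, adjusted p = 0.180 with an estimated correlation). The class I list shares Psmb8, Psmb9 and Tap1, and the class II list Ciita, with the interferon gamma list. The smallest p in the class I list belonged to Erap1, a peptide-trimming protease, at 59.05 ± 17.85 against 34.99 ± 10.27 CPM. That in the class II list belonged to H2-DMb2, a peptide-loading chaperone subunit, at 3.71 ± 1.24 against 0.903 ± 0.446 CPM. When adjusted over the list alone, 0 class I and 1 class II members passed. Libraries spread widely within groups: without control replicate 1 the medians were 1.42 and 1.67, and with the muscle level of each library as a covariate they were 0.51 and 0.58. The lowest medians in fits that left out a library were 0.63 for class I and 0.77 for class II.

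T cell genes rose as a list, with a median of 1.22 and 14 of 16 members above 0 (camera adjusted p = 1.86e-09, adjusted p = 0.171 with an estimated correlation). All 12 measured cytotoxic effector genes were above 0, with a median of 1.26 (camera adjusted p = 1.596e-10, adjusted p = 0.058 with an estimated correlation). Adjusted over the list alone, 1 T cell gene and 2 cytotoxic genes passed. Cd4, the co-receptor of helper T cells, averaged 1.33 ± 0.603 against 0.203 ± 0.135 CPM, the control libraries lying near their 3-count level. Gzmb, which encodes the cytotoxic protease granzyme B, averaged 8.07 ± 3.12 against 2.59 ± 1.28 CPM. Cd8a, the co-receptor of cytotoxic T cells, averaged 6.45 ± 4.16 against 2.03 ± 2.27 CPM with overlapping groups, a log2 fold change of 1.55 with an SE of 0.82 (edgeR adjusted p = 0.980). Over the alternatives this Cd8a fold change ran from 0.99 to 3.18. Pdcd1, which encodes PD-1, averaged 2.31 ± 1.18 against 1.02 ± 0.794 CPM, also overlapping. Without control replicate 1 the T cell median was 1.87, and with the muscle level as a covariate it was 0.59. The lowest T cell median in a fit that left out a library was 0.91.

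Regulatory T cell genes passed camera with a median of 0.46 (adjusted p = 0.0169, adjusted p = 0.180 with an estimated correlation), but the call ended without anti-LAIR1 replicate 1 (median 0.25, adjusted p = 0.0839), without anti-LAIR1 replicate 2 (adjusted p = 0.0595) and with limma-voom (0.0983). The median was 0.71 and 0.29 without control replicates 1 and 2, 0.077 without anti-LAIR1 replicate 4, 0.27 with the CPM filter, 0.25 after thinning and 0.18 with the muscle level as a covariate. Among its 8 members, Il2ra and Ctla4 passed when adjusted over the list alone: Il2ra, the interleukin 2 receptor alpha chain, averaged 3.34 ± 0.771 against 1.45 ± 0.471 CPM. Ctla4, a T cell inhibitory receptor, averaged 1.88 ± 0.941 against 0.568 ± 0.223 CPM. The list of T cell inhibitory receptors as a whole, with a median of 0.41 over 7 members, was not called (camera adjusted p = 0.136), but passed with the CPM filter (0.0227) and without anti-LAIR1 replicate 3 (0.0448).

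Macrophage and monocyte genes rose as a list, 15 of 16 being above 0 with a median of 0.57 (camera adjusted p = 2.79e-11, adjusted p = 0.058 with an estimated correlation), and 4 passed when adjusted over the list alone. Csf1r, the receptor of macrophage colony-stimulating factor, averaged 64.3 ± 8.20 against 42.5 ± 3.75 CPM, and Fcer1g, an adaptor of activating Fc receptors, 17.8 ± 1.72 against 11.4 ± 0.361 CPM. The list's mean level was higher in all 4 anti-LAIR1 libraries than in any control (exact permutation p = 0.0286, two-sided, the smallest possible, and 0.206 after adjustment over the lists), although its median was 0.23 with the muscle level as a covariate. Chemokine genes rose by a median of 0.57, with 20 of 24 above 0 (camera adjusted p = 1.66e-10, adjusted p = 0.058 with an estimated correlation). The chemokine median was 0.31 without control replicate 1 and 0.35 without anti-LAIR1 replicate 3. Complement genes rose by a median of 0.42, with 16 of 17 above 0 (camera adjusted p = 2.79e-11, adjusted p = 0.058 with an estimated correlation). Over the list alone, 5 chemokine and 4 complement genes passed. A list of pan-leukocyte genes written later, not tested with camera, had a median of 0.51 with 17 of 17 above 0. The macrophage and chemokine rises are therefore not set apart from a general leukocyte rise.

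Lair1, the receptor blocked in the treated mice, averaged 8.35 ± 1.77 CPM with anti-LAIR1 and 5.46 ± 1.85 CPM in controls (chromosome 7, 4007073 to 4073567). Its log2 fold change was 0.59 with an SE of 0.26 (edgeR adjusted p = 0.967), and the groups overlapped. The Lair1 fold change lay between 0.46 and 0.92 over the alternatives. The list of myeloid inhibitory and activating receptors that contains it rose by a median of 0.39, 19 of 20 members being above 0 (camera adjusted p = 2.10e-10, adjusted p = 0.058 with an estimated correlation). Dendritic cell genes rose by a median of 0.70 (camera adjusted p = 0.00118, adjusted p = 0.0648 with an estimated correlation), a median that was 0.22 without anti-LAIR1 replicate 4, 0.45 with limma-voom and 0.41 with the muscle level as a covariate. Itgax, the integrin CD11c, averaged 14.9 ± 3.87 against 8.61 ± 0.696 CPM. Inflammatory macrophage genes (median 0.50, camera adjusted p = 6.77e-05, adjusted p = 0.058 with an estimated correlation) and mast cell, basophil and eosinophil genes (median 0.68, camera adjusted p = 0.00250, adjusted p = 0.220 with an estimated correlation) were called higher. Without control replicate 1 both calls ended, with medians of 0.29 and 0.25, and the mast cell call also ended with limma-voom (adjusted p = 0.0527). Genes of alternatively activated macrophages were called higher near the threshold (median 0.20, camera adjusted p = 0.0453, adjusted p = 0.180 with an estimated correlation), and that call was kept in only 2 of the 7 fits that left out a library, without control replicate 2 and without anti-LAIR1 replicate 4. The median was 0.31 without control replicate 3, 0.35 without anti-LAIR1 replicate 2 and 0.31 with limma-voom, where the call ended too (adjusted p = 0.142). It also ended with DESeq2 (0.0669), with library totals (0.0961), with no filter (0.155) and with the muscle level as a covariate (median 0.11, 0.226).

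Collagen genes were lower as a list: 14 of 22 were below 0, with a median of -0.17 (camera adjusted p = 0.00205, adjusted p = 0.257 with an estimated correlation), and 0 passed when adjusted over the list alone. Col12a1, a fibril-associated collagen (chromosome 9, 79598987 to 79721141), averaged 411 ± 120 against 603 ± 70.2 CPM, a log2 fold change of -0.55 (SE 0.21, edgeR adjusted p = 0.943). The fibrillar collagens that LAIR1 binds differed less: Col1a1 averaged 791 ± 173 against 991 ± 80.8 CPM, Col1a2 638 ± 148 against 740 ± 33.7 CPM, and Col3a1 763 ± 215 against 760 ± 68.2 CPM. Their log2 fold changes were -0.33, -0.21 and 0.01, with SEs of 0.16, 0.16 and 0.20. The collagen median was -0.08 without control replicate 3 and -0.04 without anti-LAIR1 replicate 4.

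Genes of collagen processing and matrix proteins (median -0.12, camera adjusted p = 0.0418, adjusted p = 0.576 with an estimated correlation) and of the TGF beta response (median -0.15, camera adjusted p = 0.0176, adjusted p = 0.364 with an estimated correlation) were called lower, with 0 members of either passing over the list alone. Both calls ended without control replicate 1 (medians -0.086 and -0.078), control replicate 2 (-0.033 and -0.10) or anti-LAIR1 replicate 4 (0.020 and -0.059), and with limma-voom (-0.041 and -0.095), the collagen processing call also with DESeq2 (adjusted p = 0.0619) and after thinning (0.0630), and the TGF beta call also without anti-LAIR1 replicate 3 (0.0634). With the muscle level as a covariate both calls ended and the medians were 0.067 and 0.066. Without control replicate 3 and without anti-LAIR1 replicate 2 the TGF beta median was -0.25 and -0.27. Lrrc15, a marker of matrix-producing fibroblasts, averaged 34.0 ± 9.72 against 59.8 ± 8.71 CPM and separated the groups (edgeR adjusted p = 0.753). The fibroblast list that holds it was not called (median 0.08, camera adjusted p = 0.594), nor was that of matrix proteases and inhibitors (median 0.04, camera adjusted p = 0.987). Each passed as higher in 1 alternative, fibroblasts without control replicate 2 (0.0418) and matrix proteases without anti-LAIR1 replicate 4 (median 0.15, 0.0214). The 12 measured genes of the antibody targets and LAIR1 ligands passed camera as higher (median 0.39, adjusted p = 0.0287, adjusted p = 0.180 with an estimated correlation). Of these, 8 were above 0, among them Pdcd1, Cd274, Lair1 and the C1q genes. The 4 below 0 included Col1a1 and Col1a2, and the lowest log2 fold change, of another member, was -0.79. That call ended without any 1 of control replicates 2 and 3 or anti-LAIR1 replicates 1 and 3, with adjusted p up to 0.173, and it ended with no filter (0.0592) and with the muscle level as a covariate (median 0.17, 0.282). Without control replicate 1 the median was 0.67.

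Hypoxia and glycolysis genes were lower as a list, 15 of 17 being below 0 with a median of -0.19 (camera adjusted p = 2.67e-05, adjusted p = 0.284 with an estimated correlation). Ankrd37 alone passed over the list alone, and Gapdh and Ldha, which encode glycolytic enzymes, had log2 fold changes of -0.01 and -0.11. Without control replicate 2 the median was -0.030 and the call ended (camera adjusted p = 0.0573), as it did with the muscle level as a covariate, and without anti-LAIR1 replicate 4 it was -0.083. Immediate early and dissociation genes were also called lower (median -0.09, camera adjusted p = 0.0176, adjusted p = 0.403 with an estimated correlation). Dusp1, a stress-induced phosphatase, was 1 of 2 members that passed over the list alone, at 37.7 ± 5.48 against 57.9 ± 10.7 CPM. This call ended without control replicate 1 (median 0.0046, camera adjusted p = 0.148), without anti-LAIR1 replicate 3 (0.0634) and without anti-LAIR1 replicate 4 (0.975), and with limma-voom (0.638). Over the fits that left out a library its median lay between -0.17, without control replicate 2 or anti-LAIR1 replicate 2, and 0.0046. With the muscle level as a covariate the call ended too (median 0.056, camera adjusted p = 0.524).

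Endothelial genes were called higher by a median of 0.30 (camera adjusted p = 8.74e-04, adjusted p = 0.180 with an estimated correlation). Plvap, a protein of vessel fenestrae, averaged 16.8 ± 1.79 against 11.4 ± 2.87 CPM, while the call ended without anti-LAIR1 replicate 2 (camera adjusted p = 0.0751) and the median was 0.16 without control replicate 1. Proliferation genes were called higher by a median of 0.19 (camera adjusted p = 0.0119, adjusted p = 0.620 with an estimated correlation). That median was -0.016 without control replicate 1, 0.040 without anti-LAIR1 replicate 3, 0.11 without anti-LAIR1 replicate 4 and 0.072 with limma-voom, and the call ended in each. Without control replicate 3 and without anti-LAIR1 replicate 1 it was 0.32 and 0.31. Lists of epithelial (median 0.06), mesenchymal transition (-0.09), pericyte and smooth muscle (0.01), lung epithelium (0.20), plasma cell (0.18), nerve and Schwann cell (-0.20) and ribosomal protein genes (0.03) were not called. Of these the pericyte list passed as higher in 5 of 19 camera alternatives (adjusted p from 0.0110 to 0.0409), lung epithelium in 2, and the epithelial, nerve and ribosomal lists in 1 each, without control replicate 3. Neutrophil genes were not called either, and their median of -0.24 and mean of -0.03 lay below 0 while camera's direction was higher (adjusted p = 0.521). Too few members were measured to test NK cells (3 members, median 2.07), B cells (3, median 0.48), red blood cells and platelets (3, median -0.20) and skin keratinocytes (4, median -1.45), and no mitochondrially encoded mRNA was among the rows of the table. All 7 libraries held Y-linked counts, Ddx3y lying between 83.5 and 122 CPM, and low Xist, between 0.863 and 2.32 CPM.

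Genes of other tissues marked single libraries. Ttn and Neb, which encode the giant sarcomere proteins titin and nebulin, were at 94.6 and 15.3 CPM in anti-LAIR1 replicate 1, at 61.6 and 12.3 in replicate 3 and at 89.1 and 13.9 in replicate 4. In anti-LAIR1 replicate 2 they were at 8.12 and 1.596 CPM, and in controls at 2.97 to 5.54 and 1.496 to 2.44 CPM. The skeletal muscle list was called higher by camera with a median of 3.10 over 6 members (adjusted p = 5.97e-06, adjusted p = 0.180 with an estimated correlation), and its median was 4.94 without control replicate 3. The adipocyte list was called higher with a median of 1.09 (camera adjusted p = 0.0441, adjusted p = 0.403 with an estimated correlation), but without anti-LAIR1 replicate 2, where the fat cell genes Plin4 and Adipoq reached 47.6 and 5.45 CPM, its median was -0.27 and the call ended (adjusted p = 0.902). It also ended without control replicate 1 (0.351) or control replicate 3 (0.119), with limma-voom (median 0.72, 0.145), with library totals (0.0857), with no filter (0.122) and after thinning (0.0569), and the median was 2.02 with the muscle level as a covariate. Krt5 and Krt1, keratins of the epidermis, were at 40.3 and 16.4 CPM in control replicate 3 and at most 0.0863 CPM in the other 6 libraries. In anti-LAIR1 replicate 2, which lacked most of the muscle signal, the mean log2 CPM of the type I interferon list (4.04) and of the macrophage list (4.05) still lay above every control, whereas that of the MHC class I list (6.52) lay below control replicate 1 (6.71).

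**Figure D4:**
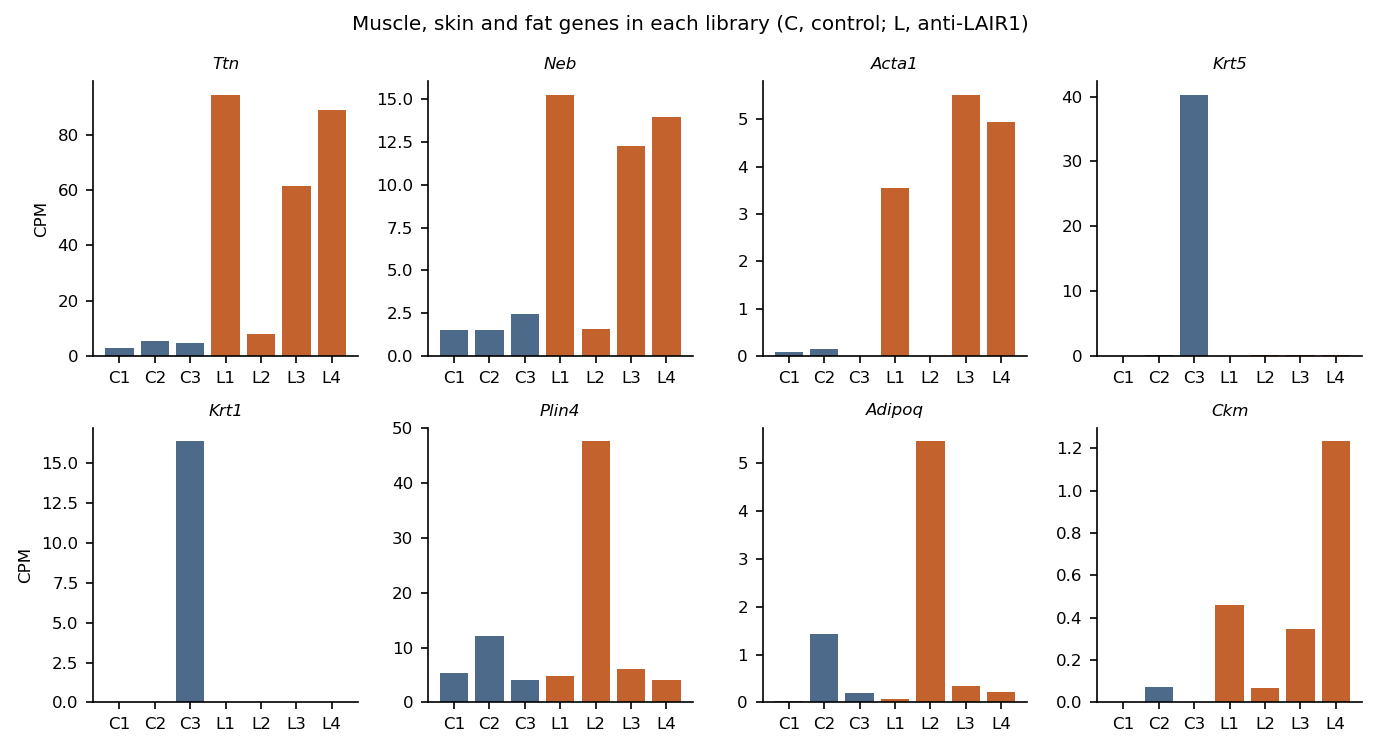
Bars give the CPM of muscle (Ttn, Neb, Acta1, Ckm), skin (Krt5, Krt1) and fat (Plin4, Adipoq) genes in each library, C1 to C3 being control and L1 to L4 anti-LAIR1 replicates. Muscle genes are high in L1, L3 and L4, keratins in C3 and fat genes in L2.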

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

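Among 89 results tested for 1 library standing apart within the 4 anti-LAIR1 libraries, 3 (3.37%) did so, and chance gives about 1 in 20. The mean log2 CPM of the epithelial list was 6.33 in anti-LAIR1 replicate 3 and 5.89 to 5.92 in the other treated libraries. The CPM of the ribosomal protein gene Rpl27 was 12.4 in anti-LAIR1 replicate 1 and 16.0 to 16.5 in the others. The mean log2 CPM of the skeletal muscle list was -1.22 in anti-LAIR1 replicate 2, far below the 2.07 to 2.13 of the other treated libraries, and it is the other 3 that differ from the controls.

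In the muscle pattern, the second of the tests below was chosen only after the result was seen. Sarcomere genes were high in anti-LAIR1 replicates 1, 3 and 4, and a candidate explanation is skeletal muscle next to those tumours taken along with them. Over 28 muscle genes kept aside for this test, the lowest of these libraries had 0.828 times the summed CPM of the highest other library, which goes against carried muscle as written in advance, but 4 of the 28 genes supplied 93.6% of the counts in the other libraries, so a small share of muscle would stay hidden. Over the 23 genes averaging under 1 CPM the ratio was 1.32, 3.62 CPM in anti-LAIR1 replicate 1 against 2.75 CPM in control replicate 3, with overlapping 95% exact Poisson intervals (2.73 to 4.71 and 1.81 to 4.00). Ckm, which encodes muscle creatine kinase, an abundant enzyme of muscle, was at most 1.24 CPM where Ttn was at 89.1 CPM, so the source of the sarcomere transcripts remains open, and no biological explanation was tested.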

How the results depend on the processing

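Alternatives with thinned counts, with the muscle level as a covariate, without Rn45s, Malat1 and Neat1, with exact permutation of list means, and DESeq2 without single libraries were chosen after seeing the data. No gene passed edgeR's adjusted test under any scaling, filter, relaxed threshold of 0.1 or covariate, or with limma-voom. DESeq2 called 54 genes, and without each library in turn it called 91, 23 and 35 (control replicates 1, 2 and 3) and 26, 65, 94 and 40 (anti-LAIR1 replicates 1, 2, 3 and 4). In the same order, 28, 18 and 23 and then 20, 36, 40 and 30 of these were among the 54, so which genes were called also changed. The cause was not tested. Leaving out libraries gave 0 to 3 genes in edgeR, 3 without anti-LAIR1 replicate 2. Camera called 17 to 27 lists over the other settings, 17 with limma-voom, where the collagen processing (adjusted p = 0.285), regulatory T cell (0.0983), alternatively activated macrophage (0.142), mast cell (0.0527), TGF beta (0.0812), proliferation (0.285), adipocyte (0.145) and immediate early (0.638) calls ended for causes not tested, and 0 with an estimated correlation, 0 with fry and 0 with exact permutation of list means, where the smallest adjusted p was 0.206. The preset correlation lies below most estimated ones (0.68 for the type I interferon list), which is part of how the first of these differs. It is not the whole difference. The dendritic cell and inflammatory macrophage calls also ended, at estimated correlations below the preset one (-0.014 and -0.0077). The rest of the cause was not tested. The type I interferon list stayed past the threshold in all 19 camera alternatives, as did both MHC lists and the interferon gamma, T cell, cytotoxic, macrophage, chemokine, complement, myeloid receptor, dendritic cell and collagen lists. No scaling moved the median fold change of all genes by over 0.1.

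With the muscle level as a covariate 18 lists were called, and median fold changes took the opposite sign to the value without it, none of these lists being called, for skeletal muscle (-0.66), collagen processing (0.067), TGF beta response (0.066), immediate early (0.056), nerve (0.073), mesenchymal transition (0.038), epithelial (-0.014), plasma cell (-0.088), proliferation (-0.042) and ribosomal protein genes (-0.045), and for neutrophils (0.089), where camera's direction did not turn. The muscle reversal follows from the construction, and the cause of the others was not tested. Lists not called otherwise passed in some alternatives: pericytes with the CPM filter (0.0409), after thinning (0.0324), with the covariate (0.0110) and without control replicate 2 (0.0328) or anti-LAIR1 replicate 1 (0.0313), lung epithelium without control replicate 2 (0.0249) or anti-LAIR1 replicate 3 (0.0448), and epithelial (0.0266), nerve (0.0266) and ribosomal (0.0278) lists without control replicate 3. Camera's direction for matrix proteases, not called under any of these, reversed with library totals (median 0.060), with no filter (0.035), after thinning (-0.0051) and without Rn45s, Malat1 and Neat1 (0.034). Leaving out single libraries turned the direction of these medians or of camera: matrix proteases (-0.11 to 0.15), fibroblasts (-0.070 to 0.17), neutrophils (-0.59 to 0.24), epithelial (-0.054 to 0.14), proliferation (-0.016 to 0.32), ribosomal proteins (-0.039 to 0.084), adipocytes (-0.27 to 1.41), collagen processing (-0.15 to 0.020), mesenchymal transition (-0.15 to 0.022), lung epithelium (-0.084 to 0.45), plasma cells (-0.10 to 0.34), pericytes and smooth muscle (-0.089 to 0.098) and immediate early genes (-0.17 to 0.0046). The pericyte median was also below 0 with no filter (-0.095), with DESeq2 (-0.096) and with limma-voom (-0.024), as was the plasma cell median with limma-voom (-0.13), camera's direction staying higher. Leaving out single libraries also turned the log2 fold change of Epor (-0.70 to 0.26), Col3a1 (-0.14 to 0.14), Plin4 (-0.52 to 1.72) and Cfd (-1.45 to 4.27). The causes were not tested, except that fewer libraries enter each such fit. No paired analysis was possible because the replicate numbers were given in accession order and link no mice across groups. Depth limits genes near 3 counts, such as Ifng and Cd4 in controls.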

Other observations

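Single genes that DESeq2 called are given here, chosen after their values were seen. None of them passed edgeR's adjusted test, and they stand for no group of genes. Myo5c, an unconventional myosin, averaged 34.2 ± 13.1 CPM (SD, n = 4) against 10.1 ± 2.39 (SD, n = 3), and DESeq2's log2 fold changes of Gpa33, Clca1, Bcas1 and Cyp4b1 were 2.48, 2.81, 1.48 and 1.23. Ly6a, the stem cell antigen Sca-1 and an interferon-inducible gene with close copies in its cluster, averaged 58.7 ± 12.3 against 22.7 ± 10.7 CPM. Ace, angiotensin-converting enzyme, was with Ankrd37 the other gene DESeq2 called lower, at 128 ± 31.1 against 222 ± 13.1 CPM. The fixed epithelial list was not called (median 0.06, camera adjusted p = 0.303). Ido1, the interferon-induced enzyme that degrades tryptophan, was at 91.0 CPM in anti-LAIR1 replicate 4 and at 2.39 to 10.3 CPM in the other 6 libraries.

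The higher type I interferon list was weighed against composition and technical explanations, and the 3 tests that compare cell-type lists were chosen only after the result was seen. Those 3 tests were not run for the interferon gamma list, for which the composition explanations stay open. Unequal depth was argued against: the type I interferon median was 1.07 after thinning all libraries to the smallest total, past camera's threshold. With the muscle level as a covariate it was 0.919, also past it, which goes against muscle tissue as written in advance. But that level was high in anti-LAIR1 replicates 1, 3 and 4 and low in replicate 2 and the controls. The adjusted value thus rests mostly on replicate 2, so muscle stays undecided. A larger leukocyte share with unchanged interferon genes per leukocyte was argued against for the type I list only. That list exceeded pan-leukocyte genes by 0.618 more in treated libraries (exact permutation p = 0.0286, the smallest possible). The same value argues against fewer tumour cells as the whole cause, since that would raise leukocyte genes as much as interferon genes. The type I interferon excess over endothelial genes (0.888, exact permutation p = 0.171) would not decide it. The macrophage excess over endothelial genes (0.260, exact permutation p = 0.343) came out as the rule written for fewer tumour cells predicts, so the tests are split. The permutation p-values of these 3 tests are unadjusted. Open for the type I list are fewer tumour cells, on which the tests are split, muscle tissue, an altered mix of leukocytes, chance and the treatment itself. So is whatever the prefixes of the mouse names stand for, which separate the groups completely. No test here could separate these.

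The libraries were also regrouped in all 35 splits of 3 against 4, and 4 results that could have come out either way were counted over them. For the number of lists camera called, 25, only the real split reached it, the highest other calling 23 and the lowest 4. That is 1 of 35 splits, the smallest share this design allows. It is rare by chance but does not exclude it, the less so with 4 results looked at. For the other 3 chance cannot be excluded either. The type I interferon median of 1.04 was reached in absolute value by 2 splits, the real one included. The other, at 1.09, grouped anti-LAIR1 replicate 3 with the 3 controls, so it differs from the real split by 1 library. The 54 genes DESeq2 called were reached by 7 splits, the highest other giving 282, and the 697 genes at an unadjusted p under 0.05 by 12, the highest other giving 1638. The edgeR count of 0 genes is reached by all 35 splits by construction and so decides nothing, the highest other being 7. Some splits thus gave more genes than the real one, so the treatment groups are not the grouping with the most differing genes. The cause was not tested. On the first principal component, which held 29.2% of the variance, anti-LAIR1 replicates 1 and 4 lay at -26.4 and -33.8 and the other 5 libraries between -4.99 and 25.2.

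Other tissue was a candidate explanation for the fat and skin genes of single libraries. Over 20 skin genes kept aside, control replicate 3 had 2.23 times the summed CPM of the highest other library, 75.6 against 33.8 CPM and 95% exact Poisson intervals that did not overlap. Over 17 fat genes kept aside, anti-LAIR1 replicate 2 had 1.47 times the CPM of the highest other library, 512 against 349, again without overlap. Both may come from tissue around the tumour. Most counts of these lists came from genes that the other tumours express too, 2 of the 20 skin genes and 6 of the 17 fat genes being at 1 CPM or more in each other library. No biological explanation was tested for either.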
